A study of Mus musculus with 6 samples.

How the data were processed

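Bulk RNA sequencing was done on CD8+ T cells sorted from tumor-draining lymph nodes of female C57BL/6J mice carrying B16F10 tumors, a transplantable mouse melanoma. The 6 libraries fall into 2 groups of 3 mice, which received HCW9218 alone or HCW9218 with an antibody against PD1. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, RNA was extracted with Trizol, mRNA was enriched with oligo(dT) beads and libraries were made with the NEBNext Ultra II RNA kit.

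Per the submitters' processing notes, STAR 2.5.2b, featureCounts, Subread 1.5.2 and DESeq2 were used. Their settings, the strand setting, the treatment of reads with several matches, the annotation release and the genome build are not given in the sources used here. The deposited counts are whole numbers of reads per gene for 49315 genes in each library, not normalized. The per-library counts and the matching columns of the deposited table of the whole series were identical in 6 of 6 libraries. A further 6 columns of that table matched no sample and were not used. The deposited normalized table, a signal in units of counts divided by a size factor, holds 15047 genes. Within a tolerance of 0.01 read, 100% of its values multiplied back to whole reads and 100% equalled the deposited counts. On these recovered reads edgeR called 142 genes higher and 20 lower. Every gene in it had a total of at least 61 counts over the 6 libraries, and the highest total outside it was 60. The deposited regularized-log table was not used.

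Of the 49315 genes, 49056 were found in GENCODE M21, an annotation of GRCm38. Of these, 44858 (91.4%) had the same chromosome, start and end, and 49048 overlapped on the same chromosome. Coordinates are printed as the deposited files give them and lie on GRCm38 by this comparison. Gene symbols come from the deposited table. Because strand use is not stated, reads of overlapping genes on opposite strands cannot be told apart.

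Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept with filterByExpr by group, which left 15142, and libraries were scaled with TMM factors between 0.901 and 1.12. A quasi-likelihood F-test of combination against monotherapy was run with no covariate, since the labels give no batch. Genes with a Benjamini-Hochberg adjusted p under 0.05 are said to have risen or fallen. The standard error of a log2 fold change is the unshrunken coefficient divided by the square root of F. CPM values are scaled by the TMM factors, and their errors are SDs over 3 mice.

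In total 30 gene lists were fixed before the data were examined, 16 of them on cell state and the others on RNA quality and on cell types the sort could hold. Each list with at least 5 tested members was tested with camera at its preset correlation of 0.01, and again with an estimated correlation and with fry. Adjustment ran over the state lists and over the other lists separately. Another 3 lists, on S100, annexin and galectin genes, NK signalling and motile cilia, were written after the data were seen.

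The rule for named genes was also fixed before the data were examined. It took genes past the threshold whose 3 combination libraries all lay above, or all below, the 3 monotherapy libraries and whose mean was at least 2 CPM. Clone-style names and immunoglobulin or T cell receptor segments were excepted. The 12 with the largest rise and the 12 with the largest fall were named, with 21 fixed genes and up to 4 members of each list with the smallest p. Of the fixed genes, Klrg1 did not pass the count filter. A few genes that the rule takes are not reported here.

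Principal components were taken over the 500 most variable genes in log2 CPM with a prior count of 2. Shannon entropy over T cell receptor V segments and the share of counts in each list were compared by exact two-sided permutation tests. With 3 mice against 3 these cannot give a p below 0.1. Floors for genes without counts are 3 counts per library and, like all counting limits, cover counting error only.

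Totals ran from 34568074 to 40101346 counts per library. On simulated counts drawn from these libraries for 14809 genes, the test called 58% of 50 genes raised 2-fold and 55.1% of 49 genes lowered to 0.5 of their level. For 1.5-fold rises it called 4% of 50 genes. Of 68 genes called, 5 had not been changed, and 0 of 15 unchanged lists of 30 genes were called. The simulated genes varied independently of each other, so lists of genes that vary together were not covered. In the real libraries the estimated correlation was 0.286 in the mitosis list and 0.498 in the type I interferon list. As a check for one library deposited under several labels, chi-square per gene was computed for each pair of libraries; it ran from 9.97 to 296, so no pair differed by counting noise alone. This check says nothing about the spread between mice.

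Alternatives covered other scalings, DESeq2 1.42.0, limma-voom, other count filters, the replicate number as a block, each library left out, gene classes left out, cell type lists as covariates and other thresholds. Alternatives chosen after the data were seen covered ribosomal share, gene length, the transcripts of Dct and Tyrp1, the recovered counts and list overlap. Same-numbered libraries were checked for pairing by the correlation of their deviations from the group means. Figures were drawn with matplotlib 3.10.9.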

Results

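CD8+ T cells from tumor-draining lymph nodes were profiled on day 5 after a single treatment given when tumors measured 50 to 100 mm3. HCW9218 is, by the series title, an immunotherapeutic complex that joins TGF-βRII and IL-15, and it was given under the skin. The monotherapy group (HCW9218, n = 3 mice) and the combination group (HCW9218 and anti-PD1 given into the peritoneum, n = 3 mice) are the only groups analysed here, so values are relative to HCW9218 alone and not to untreated mice. Depth was 38594907 ± 1492533 counts (SD, n = 3) in monotherapy and 36744251 ± 2282972 counts (SD, n = 3) in the combination. The comparison asks what adding the PD1 antibody did to the transcripts of these cells.

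With the combination, the chemokine receptor Ccr2, the granzymes Gzmm and Gzmb, the transcription factor Tbx21 and a large set of mitosis genes rose. Ccr2 went from 12.4 ± 2.37 to 64.0 ± 15.7 CPM (SD, n = 3 each), a log2 fold change of 2.37 ± 0.21 (SE). The chemokine Cxcl10 and the stress- and stimulus-induced genes Sik1, Nr4a2, Jun and Egr1 fell. Cxcl10 went from 8.79 ± 0.923 to 2.51 ± 0.709 CPM (SD, n = 3 each), a log2 fold change of -1.81 ± 0.24 (SE). In edgeR's quasi-likelihood test of 15142 genes, 144 were higher and 20 lower at an adjusted p under 0.05.

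Leaving out 1 library moved the number of higher genes to 32, 49 and 33 without monotherapy replicates 1, 2 and 3, and to 180, 69 and 233 without combination replicates 1, 2 and 3. The lower genes then numbered 4, 5 and 2, and 28, 4 and 49. Ccr2, Gzmm, Gzmb, Tbx21, Il18rap, Nusap1, Top2a, Birc5, Esco2, Pbk, Rrm2, Sik1 and Tspan9 passed whichever library was left out. Gpnmb, Klrc1, Ctla2b, Mki67, Mcm10, Cd44, Plk2, Ppp1r15a and Spsb1 did not pass whichever monotherapy replicate was left out, or without combination replicate 2, and Klf4 passed only without combination replicate 3. Cxcr3, Tyms and Tk1 did not pass whichever monotherapy replicate was left out, Ube2c, Klra10 and Cxcl10 without monotherapy replicates 1 or 3, Peg13 without 2 or 3, and Irs2 without 2 or 3 or combination replicate 2.

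**Figure D1:**
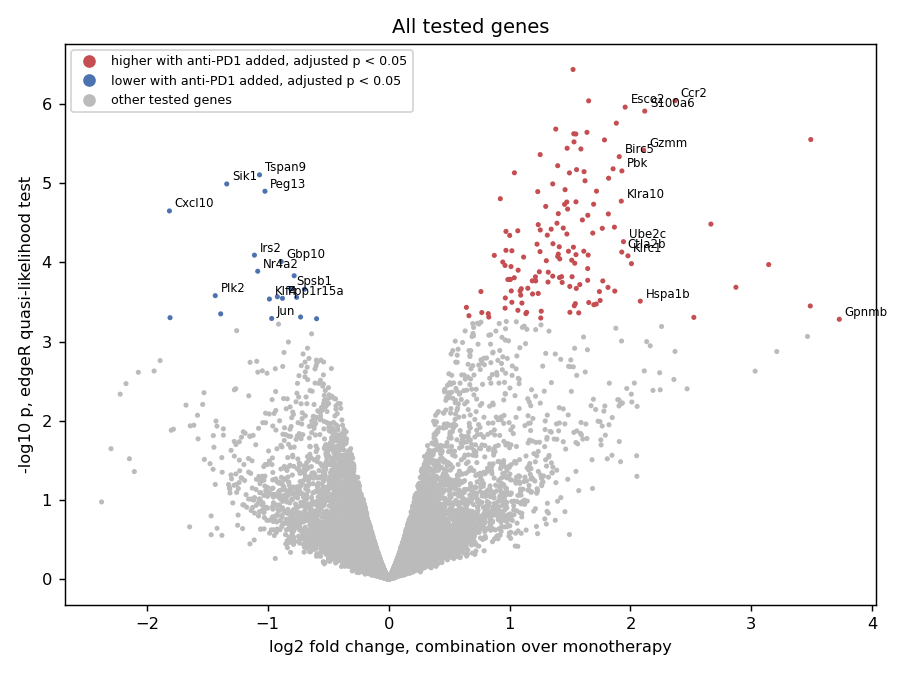
Each point is 1 of 15142 tested genes, with the log2 fold change of combination over monotherapy on the x axis and -log10 of the unadjusted p on the y axis. The 144 higher genes are red and the 20 lower genes blue, and the names are those of the 24 genes taken by the naming rule for the largest changes.

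Mitosis genes moved together. All 30 tested members of the mitosis list had a log2 fold change above 0, 25 rose and 5 did not pass, with a median of 1.48. Adjusted over the list alone, 30 of 30 were higher. Over all genes, 7, 15 and 9 rose without monotherapy replicates 1, 2 and 3, 7 with the B cell list as a covariate, and 25, 20 and 26 without combination replicates 1, 2 and 3, with list medians of 1.38 to 1.59 over the left-out libraries. Nusap1, a spindle microtubule protein, went from 9.17 ± 1.09 to 28.9 ± 2.46 CPM (SD, n = 3 each; edgeR adjusted p = 3.5e-03). Top2a, the topoisomerase that untangles replicated DNA, had a log2 fold change of 1.38 ± 0.14 (SE). Birc5, Ube2c and Mki67 rose by 1.91 ± 0.21, 1.94 ± 0.28 and 1.55 ± 0.27 (SE) on the log2 scale, and Esco2 and Pbk by 1.96 ± 0.18 and 1.93 ± 0.22. The camera adjusted p of the list was 1.05e-119 at the preset correlation, and adjusted p = 0.0147 with an estimated correlation.

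DNA replication genes had a smaller median of 0.28, and 4 of 30 rose, namely Rrm2, Tyms, Mcm10 and Tk1. Adjusted over the list alone, 10 were higher. Over all genes 1 rose whichever monotherapy replicate was left out, and 5, 3 and 7 without combination replicates 1, 2 and 3. The list had a camera adjusted p of 3.55e-11, and adjusted p = 0.0335 with an estimated correlation. Rrm2, a subunit of ribonucleotide reductase, went from 14.5 ± 1.96 to 37.2 ± 5.43 CPM (SD, n = 3 each).

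Transcripts typical of melanocytes were counted in some combination libraries and moved with this group. Dct and Tyrp1, both pigment-synthesis enzymes, together had 582 and 743 counts in combination replicates 2 and 3, and 0 in combination replicate 1. The monotherapy libraries had 1, 0 and 0 counts. The mitosis list took 0.0743%, 0.0808% and 0.113% of counts in combination replicates 1, 2 and 3, against 0.0363% ± 3.29e-03 (SD, n = 3) in monotherapy. Gpnmb, a gene of pigment cells and macrophages, had the largest rise under the naming rule, at 3.73 ± 0.73 (SE) on the log2 scale. Its call ended with Dct and Tyrp1 as a covariate, where the log2 fold change was 1.52 (adjusted p = 0.296; 2.53e-24 to 0.321 over all settings tried). With that covariate 16 of 30 mitosis genes were higher, down from 25, and the list median was 1.415. Without both libraries that held those transcripts, the list median was 1.37. That fit has 1 combination library, which is assumed to vary like the others, though the combination libraries were the more spread. No count of calls is given for it.

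**Figure D2:**
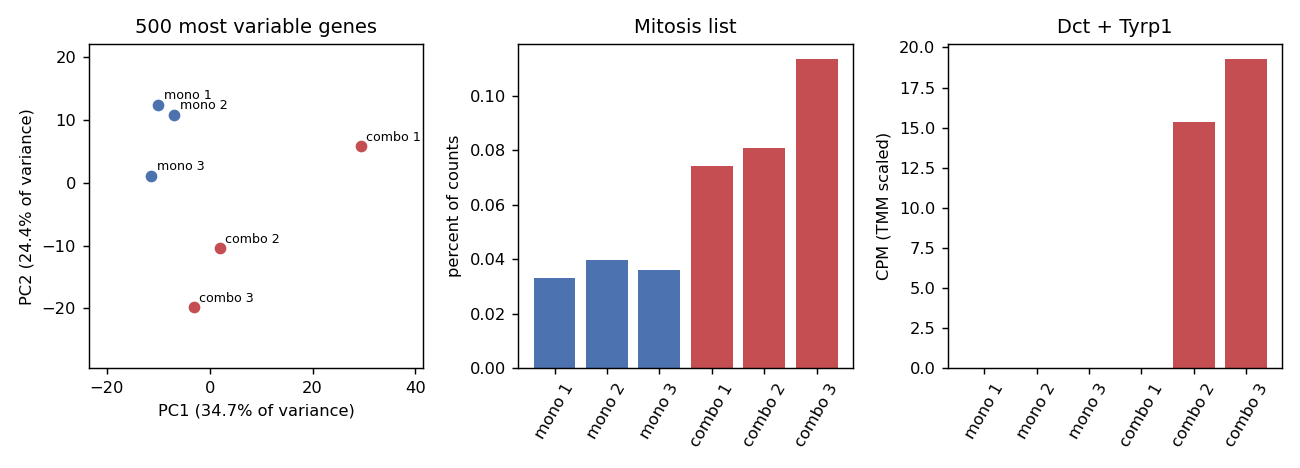
Left, libraries on the first 2 principal components of the 500 most variable genes, which carry 34.7% and 24.4% of the variance; mono is HCW9218 and combo is HCW9218 with anti-PD1. Middle and right, bars per library for the percent of counts in the mitosis list and for Dct plus Tyrp1 in CPM, which reach 15.3 and 19.3 CPM in combination replicates 2 and 3.

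Effector genes were the next group. Of 23 tested effector and cytotoxic genes, 6 rose, 0 fell and 17 did not pass, and adjusted over the list alone 8 were higher. Over all genes 3 rose whichever monotherapy replicate was left out, and 3 without combination replicate 2. Gzmm rose by 2.11 ± 0.22 (SE) on the log2 scale, and Gzmb, which induces death of target cells, went from 2.74 ± 0.251 to 8.43 ± 0.924 CPM (SD, n = 3 each). Tbx21, which encodes the effector regulator T-bet, went from 11.3 ± 2.88 to 33.0 ± 2.56 CPM. Klrc1, Gzma and Ccl5 also rose, by 1.98, 1.51 and 1.15 on the log2 scale. Prf1 and Ifng did not pass, with log2 fold changes of 0.04 ± 0.12 and 0.00 ± 0.21 (SE). Ctla2b, a protease inhibitor-like gene with a close copy in Ctla2a, rose by 1.93 ± 0.29 (SE), with the split of reads between both copies uncertain. The list had a median of 0.51, which was 0.78 without combination replicate 3, and a camera adjusted p of 3.88e-18, and adjusted p = 0.0399 with an estimated correlation. The natural killer cell list, which shares Gzma with this one, moved with it, at a median of 0.97 and a share of counts with a log2 ratio of 1.06 (camera adjusted p = 6.86e-10, and adjusted p = 0.146 with an estimated correlation).

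Receptors that guide migration rose in part. Of 25 trafficking receptors, 5 rose (among them Ccr2, Cxcr3, Cd44 and Cxcr4), 1 fell (Itgae) and 19 did not pass, and adjusted over the list alone 6 were higher and 1 lower. Over all genes 2 rose whichever monotherapy replicate was left out and 3 without combination replicate 2, and in these fits Itgae did not pass. Cxcr3, a receptor for inflammatory chemokines, had a log2 fold change of 0.92 ± 0.12 (SE). The camera adjusted p was 3.32e-05, and adjusted p = 0.104 with an estimated correlation. The list median of 0.10 was 0.16 without monotherapy replicate 1, and 0.06 and 0.24 without combination replicates 2 and 3.

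Il18rap, a subunit of the IL-18 receptor, and Gzmb were the members that rose among 24 genes of the IL-2 and IL-15 response, and adjusted over the list alone 5 were higher and 1 lower. Il18rap went from 41.5 ± 4.36 to 99.0 ± 8.21 CPM (SD, n = 3 each). Il2rb, the receptor chain shared by IL-2 and IL-15, lay at 300 ± 23.8 and 508 ± 50.1 CPM and missed the threshold in edgeR (adjusted p = 0.0515). The list median was -0.01 while its mean was 0.11 and the camera direction was up (adjusted p = 0.0327), and adjusted p = 0.262 with an estimated correlation. The call was lost without monotherapy replicate 1 (adjusted p = 0.322) and without combination replicates 1 and 3 (adjusted p = 0.0557 and 0.110), and ran from 0.0167 to 0.322 over all settings tried.

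**Figure D3:**
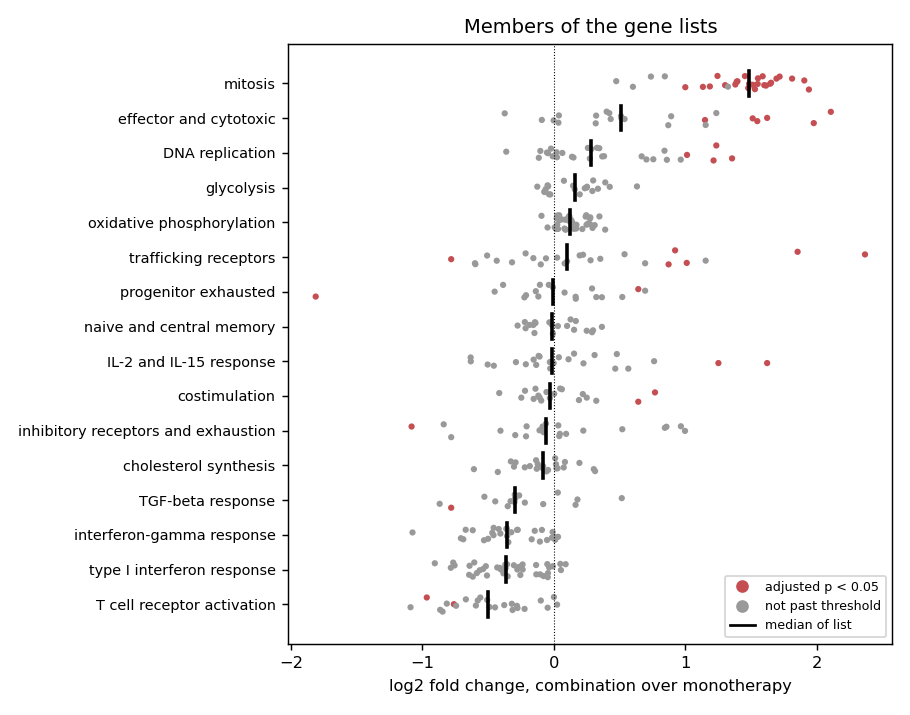
Log2 fold changes of combination over monotherapy for the members of the 16 state lists, 1 point per gene, red where the adjusted p is under 0.05, with a black bar at each list's median. The mitosis list lies highest with a median of 1.48, and the T cell receptor activation list lowest with a median of -0.50.

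Genes induced by T cell receptor signalling lay lower. Of 24 tested, 22 had a log2 fold change below 0. Egr1 and Jun fell in edgeR, and 22 did not pass. DESeq2 called 9 genes of the list lower and limma-voom 1. Adjusted over the list alone, 11 were lower. Jun and Egr1 no longer passed whichever monotherapy replicate was left out or without combination replicate 2, nor did Egr1 without combination replicate 1, where 6 genes of the list fell. Jun, a subunit of the AP-1 transcription factor, went from 359 ± 68.5 to 183 ± 29.6 CPM (SD, n = 3 each), and Egr1 from 84.2 ± 9.43 to 49.7 ± 4.11 CPM. Further named genes, none of which this list holds, also fell. Nr4a2, an orphan receptor induced by antigen signals, fell by 1.08 ± 0.18 (SE) on the log2 scale. The kinase Sik1 and the stress phosphatase subunit Ppp1r15a fell by 1.34 ± 0.16 and 0.88 ± 0.16, Plk2 and Irs2 by 1.43 ± 0.26 and 1.11 ± 0.17, and Klf4 by 0.99 ± 0.18. The tetraspanin Tspan9, the imprinted RNA Peg13 and Spsb1 fell by 1.07 ± 0.12, 1.02 ± 0.12 and 0.81 ± 0.14. The T cell receptor activation list, without those further genes, had a camera adjusted p of 2.59e-16, and adjusted p = 0.0399 with an estimated correlation.

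Heat shock genes went the other way. Of 12 tested, Hspa1a and Hspa1b rose and 10 did not pass, and adjusted over the list alone 3 were higher. Neither gene passed whichever monotherapy replicate was left out, or without combination replicate 2. Hspa1b went from 2.08 ± 0.539 to 8.81 ± 4.43 CPM (SD, n = 3 each). In combination replicates 1, 2 and 3, of which the last 2 held Dct and Tyrp1, Hspa1b was at 4.59, 8.41 and 13.4 CPM. Hspa1a and Hspa1b are near-identical copies, so the split of reads between them is uncertain. The list median was 0.23 (camera adjusted p = 1.06e-05), and adjusted p = 0.0733 with an estimated correlation; it was 0.38 without monotherapy replicate 1 and 0.46 without combination replicate 3.

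The medians of both interferon-response lists lay below 0, and no member of either passed in edgeR, though 1 of the interferon-gamma list was lower without combination replicate 1 and 1 without combination replicate 3. In the interferon-gamma list 26 of 29 genes lay below 0, 13 had an unadjusted p under 0.05, 4 were lower in DESeq2 and 0 in limma-voom. Adjusted over the list alone, 4 were lower (Irf1, Iigp1, Cd274 and Irgm1). Irf1 had 554 ± 41.2 and 348 ± 24.8 CPM (SD, n = 3 each), and Cd274, which encodes the PD1 ligand PD-L1, 67.8 ± 7.27 and 42.0 ± 8.46 CPM (edgeR adjusted p = 0.133). The camera adjusted p was 5.85e-10, and adjusted p = 0.0399 with an estimated correlation. Of 40 type I interferon genes 37 lay below 0, 11 had an unadjusted p under 0.05, and 0 passed adjusted over the list alone. DESeq2 called 1 of them and limma-voom 0. That list's camera adjusted p was 6.98e-09, and adjusted p = 0.299 with an estimated correlation, and its median of -0.36 was -0.20 without monotherapy replicate 3. Gbp10, an interferon-induced GTPase with close paralogs that neither list holds, fell by 0.89 ± 0.14 (SE) on the log2 scale. Gbp10 did not pass whichever monotherapy replicate was left out, or without combination replicate 2. The chemokine Cxcl10, with a log2 fold change of -1.81, is also in neither list, so its fall is not among their counts.

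Itgae, the CD103 integrin chain that TGF-β induces, went from 278 ± 7.77 to 162 ± 11.2 CPM (SD, n = 3 each). It was the single member to fall among 17 tested TGF-β response genes, of which 13 lay below 0 and 16 did not pass, and it did not pass whichever monotherapy replicate was left out, or without combination replicate 2. Adjusted over the list alone, Itgae and Bambi were lower. The list median was -0.29 (camera adjusted p = 9.46e-05), and adjusted p = 0.112 with an estimated correlation. Tgfbr2 had 351 ± 19.3 and 292 ± 24.1 CPM and did not pass.

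Genes of exhaustion and memory showed few calls over all genes in edgeR, though members of the exhaustion lists moved in both directions. Of 21 inhibitory receptor and exhaustion genes, Nr4a2 fell and 20 did not pass. Adjusted over the list alone 4 were higher (Cd160, Cd38, Eomes and Entpd1) and 2 lower (Nr4a2 and Cd200r1). Of the 21, 9 had an unadjusted p under 0.05, against 1211 of all 15142 genes. DESeq2 called 3 higher and 1 lower, and limma-voom 0 and 1. Nr4a2 did not pass whichever monotherapy replicate was left out, or without combination replicate 2, and 1 gene of the list was higher without combination replicate 1 and 1 without combination replicate 3. Pdcd1, the target of the antibody, had 4.91 ± 1.25 and 4.26 ± 1.35 CPM (SD, n = 3 each), a log2 fold change of -0.21 ± 0.29 (SE). Tox, Lag3 and Havcr2 had log2 fold changes of -0.21 ± 0.13, -0.11 ± 0.28 and 0.05 ± 0.46. In the progenitor exhausted list of 19, Cd28 rose by 0.64 ± 0.12, Cxcl10 fell and 17 did not pass. Adjusted over the list alone 3 were higher (Cd28, Cxcr5 and Eomes) and 1 lower (Cxcl10). Of the 19, 7 had an unadjusted p under 0.05. DESeq2 called 3 of them higher and 1 lower, and limma-voom 1 and 1. Cd28 did not pass whichever monotherapy replicate was left out, or without combination replicate 2, nor Cxcl10 without monotherapy replicates 1 or 3, and 3 and 2 genes of this list were higher without combination replicates 1 and 3. Tcf7, the transcription factor of memory and progenitor cells, was at 1301 ± 132 and 1295 ± 93.4 CPM, and Slamf6 and Eomes had 0.17 ± 0.15 and 0.52 ± 0.14. Il7r, at 0.37 ± 0.16, and Cx3cr1, at 0.54 ± 0.54, did not pass. Klrg1, a marker of terminal effectors, had 2 to 3 counts per monotherapy library and 8 to 23 per combination library and was not tested. In edgeR 0 of 20 naive and central memory genes passed, also adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 in DESeq2 and limma-voom. Median, mean and camera direction differed in sign in these 3 lists, whose camera adjusted p were 0.928, 0.615 and 0.950. Without genes shared between state lists, among them Tcf7, Tox, Cd28 and Eomes, the rest of the progenitor exhausted list passed as lower. That rest, which keeps Cxcl10, had a median of -0.14 and a camera adjusted p of 2.49e-03. It is no longer the same list, and this was the 1 of 28 other settings that passed (camera adjusted p 2.49e-03 to 0.941).

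**Figure D4:**
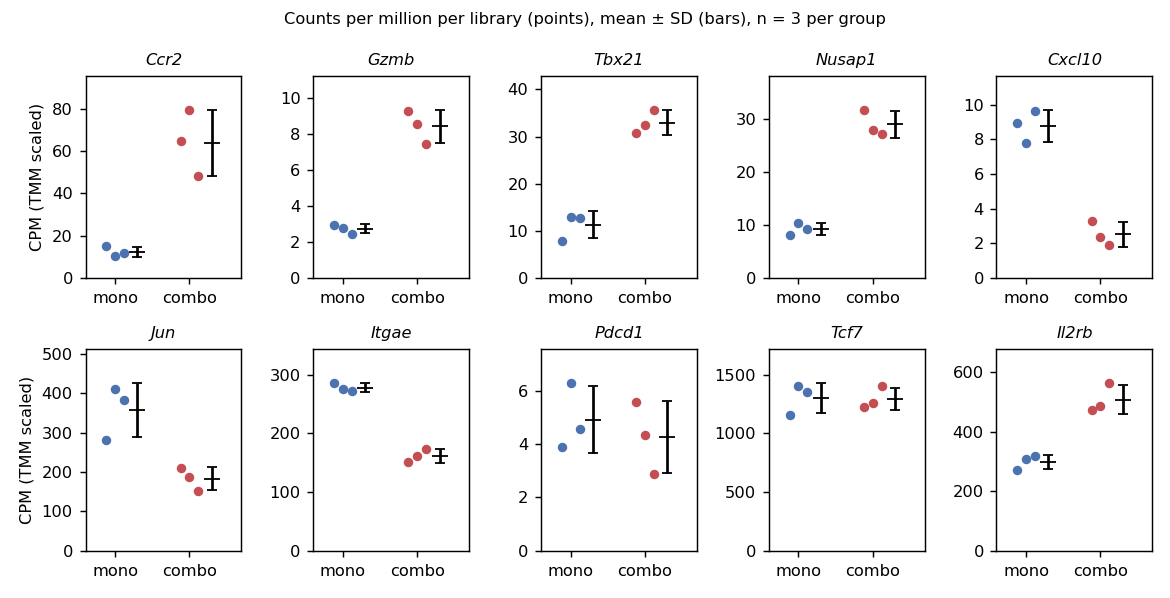
CPM per library for 10 named genes, with points for the 3 mice of each group and bars for mean ± SD; mono is HCW9218 and combo is HCW9218 with anti-PD1. Ccr2, Gzmb, Tbx21 and Nusap1 rose and Cxcl10, Jun and Itgae fell, while Pdcd1, Tcf7 and Il2rb did not pass.

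Of 19 costimulation genes, Cd28 and Tnfsf14 rose and 17 did not pass, and adjusted over the list alone 2 were higher; neither passed whichever monotherapy replicate was left out, or without combination replicate 2, nor did Tnfsf14 without combination replicate 1; the camera adjusted p was 0.233. Glycolysis, oxidative phosphorylation and cholesterol synthesis had 0 calls in edgeR, over all genes or adjusted over the list alone, with 1, 0 and 2 genes at an unadjusted p under 0.05. DESeq2 called 0, 0 and 1 of them and limma-voom 0. Their camera adjusted p were 0.0511, 0.121 and 0.169, and over 28 other settings 0.0143 to 0.299, 2.93e-17 to 0.960 and 0.0314 to 0.491. Glycolysis passed in 11 of these settings, among them limma-voom (adjusted p = 0.0178), DESeq2 (adjusted p = 0.0444) and without combination replicate 3 (adjusted p = 0.0143), and cholesterol synthesis in 1. Oxidative phosphorylation passed in 8, as higher without monotherapy replicate 1 (median 0.18, adjusted p = 0.0235) and combination replicate 3 (median 0.37, adjusted p = 6.61e-09) and as lower without combination replicate 1 (median -0.083, adjusted p = 0.0240).

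Markers of other cells were low and moved in both directions. Of 13 CD8 identity genes 0 passed in edgeR, over all genes or adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 in DESeq2 and limma-voom. Cd8a was at 1533 ± 113 and 1496 ± 80.4 CPM (SD, n = 3 each) and Cd8b1 at 1250 ± 222 and 1311 ± 308 CPM. In the natural killer cell list Klre1, Gzma and Klra3 rose and 12 of 15 did not pass, and adjusted over the list alone 7 were higher (camera adjusted p = 6.86e-10, and adjusted p = 0.146 with an estimated correlation). Over all genes these 3 did not pass whichever monotherapy replicate was left out, or without combination replicate 2, nor did Klra3 without combination replicate 1. Klra3 and Klra10 belong to a family of near-identical receptor genes, so their separate values are uncertain. Among 18 B cell genes Cd22 rose, also adjusted over the list alone, but did not pass whichever monotherapy replicate was left out or without combination replicate 2, while 15 lay below 0 (median -0.47, camera adjusted p = 6.20e-03, and adjusted p = 0.785 with an estimated correlation). That median was -0.73 and -1.43 without monotherapy replicate 1 and combination replicate 2, and the call was lost without monotherapy replicate 2 (-0.28, adjusted p = 0.0759) and combination replicates 1 and 3 (-0.20 and -0.33, adjusted p = 0.305 and 0.121; 3.60e-13 to 0.876 over all settings tried). All 10 plasma cell genes lay below 0 and Ighg2b fell, also adjusted over the list alone, but passed with a library left out only without combination replicate 3 (camera adjusted p = 9.96e-05, and adjusted p = 0.0733 with an estimated correlation). In the gamma-delta list of 11, Cd163l1 rose by 1.47 ± 0.21 (SE), also adjusted over the list alone, but did not pass without monotherapy replicates 1 or 3, and Trdc did not pass at -0.35 ± 0.16. The CD4 and regulatory T cell and class II antigen presentation lists lay below 0 at the preset correlation (camera adjusted p = 0.0390 and 0.0108), with adjusted p = 0.522 and adjusted p = 0.540 with an estimated correlation. Both calls were lost without monotherapy replicate 2 (adjusted p = 0.137 and 0.0759) and combination replicate 3 (adjusted p = 0.0792 and 0.142), and the first also without monotherapy replicate 3 (adjusted p = 0.0611); the class II median of -0.49 ran from -0.81 to -0.31 with a library left out. Over all settings tried these lists ran from 2.10e-03 to 0.522 and from 1.96e-06 to 0.610. By share of counts, which the most abundant members set, the log2 ratios of the CD4 and B cell lists were 0.065 and 0.051 and that of the gamma-delta list 0.51, against list medians of -0.29, -0.47 and -0.15, and that of class II was -0.37. Myeloid and stromal lists did not pass (camera adjusted p = 0.306 each), nor did the ribosomal and mitochondrially encoded lists (0.789 each), but single libraries changed this. Without monotherapy replicate 3 the myeloid list was higher (median 0.51, adjusted p = 5.86e-03) and the stromal list lower (-0.78, adjusted p = 0.0120), as the latter was without combination replicate 2 (-1.19, adjusted p = 0.0156). Without combination replicate 3 the ribosomal and mitochondrially encoded lists were higher (0.36 and 0.42, adjusted p = 1.83e-07 and 8.49e-05), and without combination replicate 1 the ribosomal list was lower (-0.29, adjusted p = 1.48e-06). The highest adjusted p over all settings tried were 0.897, 0.947, 0.988 and 0.974 for these 4 lists. Melanoma and erythroid lists had 4 tested members each and were not tested as lists.

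Ribosomal protein genes took 7.66% ± 0.585 of counts in monotherapy and 7.91% ± 2.98 in the combination (SD, n = 3 each; exact two-sided permutation p = 0.8). The combination libraries were the more spread, at 10.96%, 7.78% and 5.00%. Pairs of libraries correlated across genes at 0.987 to 0.989 within monotherapy, 0.968 to 0.982 within the combination and 0.975 to 0.985 between the groups. Combination libraries were thus no more alike among themselves than some were to monotherapy libraries. Combination replicate 1 stood apart on the first component, at 29.3 against values from -11.3 to 1.94 in the other libraries.

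Shannon entropy over Trbv segments was 4.08 ± 0.0141 bits in monotherapy and 4.10 ± 0.0181 in the combination (SD, n = 3 each; exact two-sided permutation p = 0.3). Over Trav segments it was 5.66 ± 0.0355 and 5.63 ± 0.0233 bits (exact two-sided permutation p = 0.3). The smallest p that 3 mice against 3 allow is 0.1.

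By position on GRCm38, Ccr2 (ENSMUSG00000049103) lies on chromosome 9 from 124101950 to 124113557 and Cxcl10 (ENSMUSG00000034855) on chromosome 5 from 92346638 to 92348889, where its exons overlap those of Art3. Gzmb lies on chromosome 14 from 56258856 to 56262260, Tbx21 on chromosome 11 from 97098071 to 97115331 and Itgae carries the identifier ENSMUSG00000005947. Each of these 5 is annotated as protein-coding.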

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

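Counts above the limit of 3 that a count of 0 allows appeared in genes that the count filter kept out of the comparisons. Dct and Tyrp1 together had 582 counts in combination replicate 2 and 743 in combination replicate 3. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 48, 490 and 6 counts in monotherapy replicates 1, 2 and 3, and 1, 0 and 0 in the combination libraries, while the labels give all mice as female. Xist had between 8391 and 35032 counts in the 6 libraries.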

How the results depend on the processing

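Deviations of same-numbered libraries correlated at 0.145, -0.0551 and 0.279 for numbers 1, 2 and 3. Numbers 1 and 3 correlated best with their own number and number 2 did not, and the labels do not pair the mice, so the numbers were not taken as pairs. With the number as a replicate block 231 genes were higher and 57 lower, and the IL-2 and IL-15 list no longer passed (adjusted p = 0.0515). Of the other planned settings, those that moved a count by over 1.5 times gave, higher and lower, 282 and 72 (DESeq2), 340 and 113 (no filter beyond 1 count), 30 and 1 (B cell list as covariate) and 75 and 4 (myeloid and dendritic list as covariate). Against a 1.2-fold change 114 genes were higher and 8 lower. Other scalings, limma-voom, the filter at 1 CPM and gene classes left out gave 116 to 150 higher and 14 to 20 lower, and an adjusted p under 0.1 gave 198 and 27. Settings chosen after the data were seen gave 393 and 221 (ribosome list as covariate), 89 and 32 (Dct and Tyrp1 as covariate), 834 and 628 (both libraries with those transcripts left out), 175 and 24 (gene length trend removed) and 152 and 26 (combination replicates 1 and 3 left out). Fits with 2 libraries left out have 1 combination library, which is assumed to vary like the others. The cause was not tested. Leaving out each library gave 32 to 233 higher and 2 to 49 lower genes. Of the 44 genes named by the first parts of the rule, 27 passed; 10 to 29 did with a library left out, and 9, 14 and 16 with the B cell, myeloid, and Dct and Tyrp1 covariates. All 24 genes of the largest changes kept their sign with each library left out, and 8 of them passed each time.

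Of the 16 state lists 9 passed, 9 or 10 with a library left out, 5 with an estimated correlation and 7 with fry. The share of higher genes, 87.8%, was 87.9% to 88.6% with the other scalings and the median of all genes stayed within 0.02. Camera direction reversed for oxidative phosphorylation (median -0.083) and cytosolic ribosome (-0.29) without combination replicate 1 (ranges with a library left out -0.083 to 0.37 and -0.29 to 0.36). For the B cell list it reversed with combination replicates 1 and 3 left out (0.18), a fit with 1 combination library. It also did with that list's own values as covariate, which fixes the outcome in advance, and the median of -0.071 kept the sign of the main -0.47. Without genes shared between lists, among them Tcf7, Tox, Cd28 and Eomes, the rest of the progenitor exhausted list passed as lower (-0.14, camera adjusted p = 2.49e-03). The whole list had a camera adjusted p of 0.615. Its main camera direction was up, though the main median of -0.007 already lay below 0. Differences in V segment entropy ran from 8.63e-03 to 0.0267 bits (Trbv) and from -0.0483 to -0.0146 bits (Trav) with a library left out.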

Other observations

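Tests on the melanoma transcripts, on handling stress, on natural killer cells and on Klra reads, and the ribosome and length corrections, were chosen after the data were seen.

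Single members of 2 further lists, both written after the data were seen, passed. As with the NK signalling list below, their list p-values and list-alone calls describe the same data and are no independent test. S100a6, a calcium-binding protein, went from 7.05 ± 0.646 to 30.6 ± 7.48 CPM (SD, n = 3 each), and Anxa2 from 26.3 ± 0.162 to 62.8 ± 15.1 CPM. They were the 2 of 22 S100, annexin and galectin genes that passed in edgeR, 5 adjusted over the list alone (adjusted p = 0.0790 with an estimated correlation). Among 30 motile cilium genes Armc2, Drc1, Wdr31 and Wdr95 rose, also adjusted over the list alone, with Armc2 at 0.222 ± 0.0239 and 2.53 ± 0.560 CPM. Of that list 16 lay above 0 and 14 below, and its median was 0.03 (camera adjusted p = 4.98e-03, and adjusted p = 0.0665 with an estimated correlation). The list of NK signalling genes, of whose 8 tested members 7 are also in the NK list, had a median of 0.40 (camera adjusted p = 7.10e-03, and adjusted p = 0.135 with an estimated correlation).

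Mitosis genes were higher in all 3 combination libraries. The list median was 1.47 with the ribosome covariate and 1.47 with the length trend removed, against 1.48. Mean ribosomal share differed little between the groups, at 7.66% and 7.91%, so that covariate could hardly move the median and decides nothing. Removing the length trend moved genes by 0.0153 on average on the log2 scale. A length trend of that size is argued against as the whole cause. Melanoma cells carrying Dct and Tyrp1 are argued against as the source in combination replicate 1, which had 0 counts of both. Cells without these transcripts are not excluded there, and Gpnmb had 36 counts in it against 6, 18 and 26 in monotherapy. In replicates 2 and 3, where the rise was 1.60 times that of replicate 1, melanoma cells may have added a part. No biological explanation was tested, and an effect of the added antibody stays open.

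T cell receptor activation genes were lower in the combination. Handling stress that raises immediate-early and heat shock genes together in monotherapy is argued against by the heat shock list, whose median was 0.23 with 12 of 12 members above 0. It is not excluded, since that list did not pass with an estimated correlation (camera adjusted p = 0.0733). Hspa1b was also highest in combination replicates 2 and 3, which held Dct and Tyrp1. The list median was -0.52 with the ribosome covariate and -0.50 without. As mean ribosomal share was 7.66% and 7.91%, that covariate could hardly move the median and decides nothing. With Dct and Tyrp1 as a covariate the median was -0.348 (camera adjusted p = 7.14e-05). It was -0.343 without combination replicates 2 and 3, which held those transcripts, in a fit with 1 combination library. Whether tumor material added to the fall was not tested. A difference in time or handling that spares heat shock genes may still be a source, because no processing day is given in the labels, and an effect of the added antibody stays open, as untested.

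In sum, NK receptor genes lay higher in the combination. Of the 6 Klra, Klre and Klri genes of the NK list, Klre1 and Klra3 passed, and neither did whichever monotherapy replicate was left out. The whole list had a camera adjusted p of 0.146 with an estimated correlation. Summed over 14 Klra genes the level was 59.8 ± 9.63 CPM in monotherapy and 188 ± 19.1 in the combination (SD, n = 3 each), a log2 ratio of 1.654, and a shift of reads among these 14 does not change their sum; the pseudogene Klra13-ps, named after its values were seen, carried 33.1 ± 7.04 and 122 ± 14.6 CPM of it, and the 11 Klra genes that are not pseudogenes 26.4 ± 4.19 and 65.2 ± 19.4, where the lowest combination library, 44.09, lay above the highest monotherapy library, 31.17, by less than the SD within groups of 14 (log2 ratio 1.31), so for these 11 alone a shift of reads is not excluded. Natural killer cells in the sort cannot be told apart from CD8+ T cells carrying these receptors: in sum, the 6 Klra, Klre and Klri genes of the NK list lay 23.85 ± 7.41 CPM higher with the combination and its other 9 members 9.999 ± 1.81 CPM (SE, n = 3 each), and the ranges of 2 SE around both values overlap. Of those 9, the abundant NK adaptors Tyrobp and Fcer1g had 0.964 ± 0.357 and 0.941 ± 0.229 CPM in monotherapy and 1.57 ± 0.212 and 1.03 ± 0.197 CPM in the combination (SD, n = 3 each), and Gzma, which the effector list also holds, 3.69 ± 0.425 and 10.5 ± 2.95 CPM. Of the 15 tested members of the NK list 13 lay above 0. Ncr1 and Klrb1f lay below, at log2 fold changes of -0.159 and -0.161, and Ncr1 had at most 13 counts per library. The sort on CD8 selects against natural killer cells, and an effect of the added antibody was not tested.

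Other splits of the 6 libraries gave at most 0 genes past the threshold, against 164 for the real groups, and at most 8 state lists, against 9. The real split was the 1 of 10 with as many in each case, and 10 splits are too few for a share under 0.05. Each other split also mixes libraries of both treatments, so a true difference would widen the spread within groups and lower the calls. The comparison with these splits therefore decides nothing about chance. In them the camera adjusted p of the mitosis list at the preset correlation ran from 1.84e-18 to 0.235.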
